A study of Danio rerio with 2 samples.

How the data were processed

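Tails of zebrafish embryos (strain AB, TgBAC(isl1:TagRFP) with Tg(dab2:EGFP)) were dissociated at 48 h post fertilisation, and live cells were sorted on TagRFP and EGFP, per the labels' protocols. Libraries were made with the 10x Genomics Chromium Single Cell v3.1 reagents, which count RNA 3' ends by UMI, and sequenced on an Illumina NovaSeq6000, per the labels. There were 2 samples in 2 groups, 1 library each, and groups were taken from the sample labels. The deposited values are UMI counts per gene and barcode, whole numbers with no normalization, which the authors made with Cell Ranger on genome build GRCz11. The submitters' processing notes name version 5.0.0 and the matrix headers version 5.0.1. The feature list holds 27421 features and ends with the 2 transgene features TagRFP and GFP. The deposited barcodes had at least 500 and 519 UMIs, so they had been reduced to called cells before.

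Gene symbols were used as the feature list gives them, and the name table at hand held 24988 of the feature IDs. The 1174 features that share a symbol with another feature were summed per symbol, which left 26764 symbols, so near-identical copies with 1 name cannot be told apart. No coordinates are given, because the reference table at hand is of another build.

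A barcode was kept with at least 500 genes and under 10% mitochondrial UMIs, which removed 42 and 21 barcodes of the libraries labelled isl1-derived and other. Doublets were called per library with Scrublet in scanpy 1.11.5 (automatic threshold), and 7 and 6 called barcodes were removed, a low share that leaves undetected doublets possible. Counts were scaled to 10000 per cell and log1p transformed, 2000 variable genes were scaled and clipped at 10, and 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9) gave 19 clusters. Endothelial-like cells were clustered again alone with these settings.

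Clusters were named from 13 marker lists. A marker counted as present with a UMI in at least 25% of the cluster's cells and a level of at least 25% of the highest cluster. A list with at least 3 of the 10 leading genes by fold gave the name, otherwise the list with the highest share of markers present, and a cluster stayed unnamed with under 3 markers present, with more leading genes of another list, or when shallow and without a marker among its leading genes, which removed no cluster. The markers were fixed before the data were examined, while this order of steps was set after the first clustering. It kept 1 cluster out of every class, with 4.65% and 6.26% of the cells.

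UMIs were summed per library and class. Levels are CPM (a gene's UMIs scaled to the sum over all genes), with exact Poisson intervals, shares have exact binomial (Clopper-Pearson) intervals, and CPM ratios have exact conditional binomial intervals, all at 95%. Ratios are those of the library labelled isl1-derived over the library labelled other. Log2 ratios were taken with 0.5 added to each count. A gene was measured with at least 100 UMIs in both sums together. Genes were described by size alone, at a ratio of 2 across all genes and of 1.5 within lists, which is no call of change. Members of 22 programme lists and of the marker lists were compared by their median log2 ratio, where at least 3 were measured, and its percentile among 10000 random lists drawn from 20 bins of expression. A count of 0 was bounded with 3 counts, a one-sided 95% limit, while intervals are two-sided. Classes and subclusters were compared with at least 50 cells in each library.

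The genes named were fixed by a rule before the data were examined. It takes isl1, dab2 and the reporter features, then the 12 genes of each direction ranked by the interval bound nearest 1, leaving out clone names, mitochondrial and ribosomal protein genes, and for each list up to 4 members with most UMIs and up to 2 with the largest ratio, with some left out of the text for length. Clusters are described by their leading 10 genes by fold. Within subclusters the genes are the leading 3 of each direction and list members. The list members prox1a, lyve1a, cdh6 and unc5b, the levels of single genes per cluster and the lyz, hbae3 and hbbe3 levels per class were chosen after their values were seen.

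The ratio step was tested on simulated counts with 200 genes changed 4-fold. For endothelial-like cells (9274 genes) 100% of raised and 100% of lowered genes came out beyond a ratio of 2, with 0.0112% of unchanged genes. Intervals held the true ratio for 95.7% of unchanged genes. For blood progenitor-like cells (7730 genes) these were 100%, 100%, 1.66% and 96.1%. Random lists without change fell outside the central 95% of percentiles in 3.5% and 6% of draws.

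The alternatives were no barcode filter, at least 1000 genes with under 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2.0, TMM scaling (edgeR 4.0.16 in R 4.3.3), haemoglobin genes left out, minimums of 30 and 300 UMIs, equal weight per cell, equal weight per subcluster with at least 20 cells of each library, and every cell thinned to 2000 UMIs, which left out 75 and 39 shallower cells. Chosen after seeing the data were the unnamed cluster counted as endothelial, the subcluster with over 2 times the class's median UMIs left out, a clustering without 1494 listed or differing genes, the 3 cells with the most TagRFP or isl1 UMIs left out, both weightings of subclusters with at least 5 cells of each library, and the thinned and subcluster-weighted forms of the list medians. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.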

Results

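The series holds single-cell RNA sequencing of zebrafish tails at 48 h post fertilisation. The embryos carried 2 transgenes, TagRFP under regulatory sequence of isl1, a LIM homeodomain transcription factor gene, and EGFP under that of dab2, a clathrin adaptor gene of venous and lymphatic endothelium. Live cells were sorted into a TagRFP-positive, EGFP-positive fraction, labelled isl1-derived endothelial cells, and a TagRFP-negative, EGFP-positive fraction, labelled the other endothelial cells. Each fraction gave 1 library. The design sets the 2 fractions against each other, to ask how endothelial cells descended from isl1-expressing progenitors differ from the rest of the tail endothelium. With 1 library per fraction there are no replicates, so no test was run, and every interval given covers counting error only.

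The library labelled isl1-derived held 2072 barcodes and 26865577 unique molecular identifiers (UMIs), and the library labelled other held 730 barcodes and 5698957 UMIs. After filtering, 2023 and 703 cells were kept, with a median of 9780 UMIs and 2779 genes per cell in the first and 6618 UMIs and 2349 genes in the second.

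The transcripts that define the sort ran against the labels. TagRFP RNA stood at 2.71 CPM (95% exact Poisson interval 2.12 to 3.41) over all kept cells of the library labelled isl1-derived, which the sort should have enriched for it, and at 132 CPM (122 to 142) in the library labelled other. Endogenous isl1 showed the same order, with 1.96 CPM (1.46 to 2.56) against 131 CPM (122 to 141). Within endothelial-like cells, TagRFP reached 4.46 and 30.4 CPM, a ratio of 0.147 (0.103 to 0.206), and isl1 reached 2.14 and 24.7 CPM, a ratio of 0.0866 (0.0525 to 0.137). The names of the deposited files also read opposite to the sample labels. Groups below follow the labels, the libraries are called by their labels throughout, and every direction given between them carries this conflict.

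Most TagRFP and isl1 UMIs of the library labelled other lay in 22 neural-like cells. TagRFP stood at 2678 CPM there, with 506 UMIs in 17 cells, and isl1 at 3086 CPM, with 583 UMIs in 18 cells. In endothelial-like cells a TagRFP UMI was present in 3.05% of cells (38 of 1245, exact binomial interval 2.17% to 4.17%) of the library labelled isl1-derived and in 9.94% (54 of 543, 7.56% to 12.8%) of the library labelled other. With every cell thinned to 2000 UMIs, which left out 75 and 39 shallower cells of the libraries, these shares were 1.09% (0.582% to 1.86%) and 2.92% (1.65% to 4.78%), with overlapping intervals, and the TagRFP levels were 5.88 CPM (3.21 to 9.86) and 26.3 CPM (17.3 to 38.3). Thinned shares with an isl1 UMI were 0.252% (0.0520% to 0.734%) and 3.12% (1.79% to 5.02%).

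A few cells held many of these UMIs. In the library labelled other, 3 cells held 38.5% of the 122 endothelial-like TagRFP UMIs and 3 cells held 64.6% of the 99 isl1 UMIs. Without the 3 leading cells of each library, an alternative chosen after seeing the data, the endothelial-like TagRFP ratio was 0.188 (0.124 to 0.281) and the isl1 ratio 0.0529 (0.0162 to 0.136). After thinning, the TagRFP levels without such cells were 4.21 CPM (2.02 to 7.74) and 12.7 CPM (6.79 to 21.8), with overlapping intervals and a ratio of 0.330 (0.130 to 0.815), and isl1 had 0 and 13 UMIs.

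Blood progenitor-like cells, taken as a background class, differed between the libraries in the same direction. Their TagRFP levels were 1.65 CPM (1.01 to 2.54) and 20.6 CPM (12.4 to 32.2) without thinning. Their thinned TagRFP shares were 0.549% (0.113% to 1.60%) and 6.15% (1.70% to 15.0%), from 3 and 4 cells, and their thinned isl1 shares 0.183% and 6.15%, from 1 and 4 cells. Their unthinned median depths were 21860 and 11827 UMIs against 8106 and 6655 UMIs in endothelial-like cells. At matched depth, TagRFP in this class stood at 6.41 and 61.5 CPM, and isl1 in the library labelled other at 30.8 CPM (8.38 to 78.8) against 31.2 CPM (21.3 to 44.0) in endothelial-like cells. The endothelial-like shares and levels were thus not detectably above this background at matched depth. The background held 8 TagRFP and 4 isl1 UMIs in that library, too few to exclude an endothelial-like excess, and 3 cells held 87.5% of the 8. Thinning also gives every cell equal weight, which by itself can change the level of a mixed class. At full depth the TagRFP intervals of the 2 classes overlapped in the library labelled other only, and the isl1 intervals in neither library. Full-depth isl1 in the library labelled other was 8.68 CPM (3.75 to 17.1) in the background and 24.7 CPM (20.1 to 30.1) in endothelial-like cells. Without the 3 leading endothelial-like cells the latter was 8.81 CPM (6.14 to 12.3). As 1 of the blood progenitor-like clusters carries endothelial transcripts, the class is an imperfect background.

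As a class, endothelial-like cells of both libraries carried more EGFP and dab2 RNA than blood progenitor-like and neural-like cells. The EGFP feature, listed as GFP, stood at 1299 CPM (1277 to 1321) in the library labelled isl1-derived and 1963 CPM (1919 to 2006) in the library labelled other, and dab2 at 1297 CPM (1276 to 1319) and 2660 CPM (2610 to 2711). Blood progenitor-like cells held 108 and 206 CPM of GFP, and neural-like cells 68.8 CPM. A cluster left unnamed held the most GFP, at 3609 and 3301 CPM. Levels also differed within the endothelial-like class. Its cluster led by esm1 and kif26aa (275 and 28 cells) had GFP at 261 CPM and dab2 at 149 CPM. Its cluster led by gpm6aa and cobll1b (56 and 5 cells) had 120 and 55.2 CPM.

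**Figure D1:**
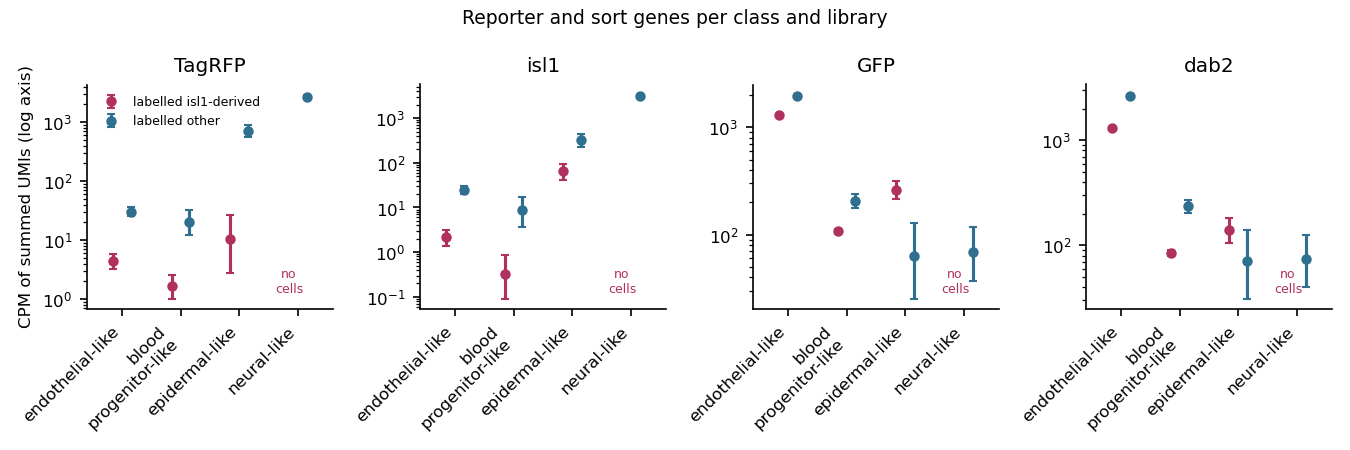
CPM of summed UMIs (log axis) of TagRFP, isl1, GFP and dab2 in 4 classes of cells, with points for the 2 libraries and bars for 95% exact Poisson intervals. In endothelial-like cells TagRFP lies at 4.46 CPM in the library labelled isl1-derived and 30.4 CPM in the library labelled other, and the neural-like cells of the latter lie at 2678 CPM.

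Endothelial-like cells made up most of both libraries. They were 61.5% (1245 of 2023 cells, exact binomial interval 59.4% to 63.7%) of the library labelled isl1-derived and 77.2% (543 of 703, 74.0% to 80.3%) of the library labelled other. Blood progenitor-like cells, with myb, runx1 and gata2b transcripts, made up 27.4% (25.5% to 29.4%) and 9.82% (7.72% to 12.3%). Erythroid-like cells were 3.46% (2.71% to 4.35%) and 0.711% (0.231% to 1.65%). Their cluster also had 7 of 11 blood progenitor markers present. Among its 75 cells, hbae1.3 UMIs were in 94.7%, hbae3 UMIs in 38.7% and hbbe3 UMIs in 25.3%. Its 5 cells of the library labelled other held 0 hbae3 UMIs and myb at 394 CPM, so the name is weak for them. Myeloid-like cells led by lyz, npsn and mmp13a, genes of neutrophils, were 1.14% (0.722% to 1.70%) and 0.427% (0.0881% to 1.24%). Cells of the epidermal-like cluster were 1.78% (1.25% to 2.46%) and 2.42% (1.41% to 3.84%). This cluster was mixed, with krt4 UMIs in 26.4%, krt5 UMIs in 34.0% and epcam UMIs in 41.5% of its 53 cells and col1a2 at 4327 CPM. Neural-like cells led by chata, slc18a3a and slc5a7a, genes of cholinergic neurons, were 0 of 2023 cells in the library labelled isl1-derived, which allows a share of up to 0.148%, and 3.13% (1.97% to 4.70%) in the library labelled other. A cluster led by tnnt3a and crygn2 stayed unnamed, because a muscle gene led it although 14 of 27 endothelial markers and dab2 at 3162 CPM were present, and it held 4.65% and 6.26% of the cells. The shares describe cells that passed the sort, not the tail, and the libraries differed in depth.

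**Figure D2:**
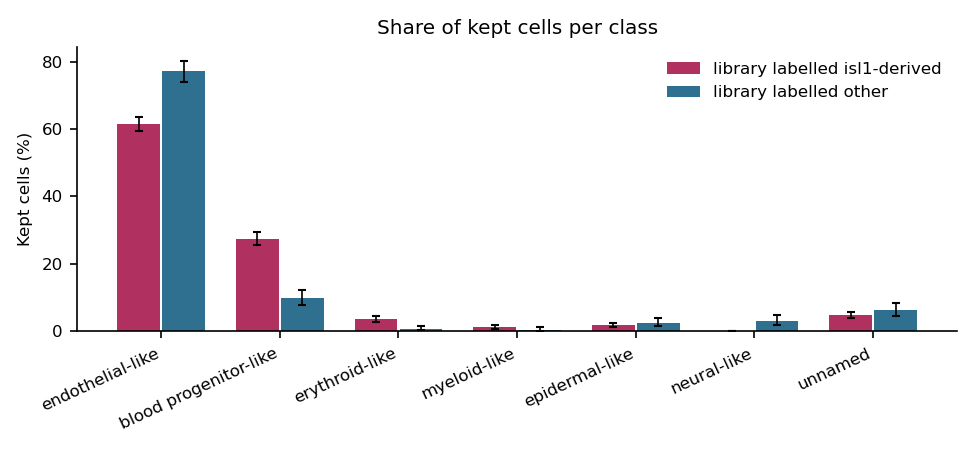
Percent of kept cells per class (bars) in each library, with 95% exact binomial intervals. Endothelial-like cells make up 61.5% and 77.2%, blood progenitor-like cells 27.4% and 9.82%, and neural-like cells 0% and 3.13% of the libraries labelled isl1-derived and other.

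In endothelial-like cells summed per library, arterial and tip cell genes were higher in the library labelled isl1-derived, and venous, scavenging and blood niche genes were higher in the library labelled other. Of 11 measured arterial genes, 10 were at least 1.5-fold higher in the library labelled isl1-derived, among them the water channel gene aqp8a.1 (6138 against 3037 CPM, ratio 2.02, interval 1.98 to 2.06), the decoy VEGF receptor gene flt1 (404 against 195 CPM, ratio 2.07) and the Notch ligand gene dll4 (ratio 1.60). The chemokine receptor gene cxcr4a had a ratio of 3.17, and unc5b was the exception at 0.551. Of 12 angiogenic tip genes, 7 were at least 1.5-fold higher, including esm1 (765 against 208 CPM, ratio 3.67, interval 3.42 to 3.95) and angpt2a (ratio 5.96, interval 2.64 to 16.6), while aplnra was lower at 0.563. The tip list shares dll4 and cxcr4a with the arterial list. Of 15 venous and caudal plexus genes, 9 were at least 1.5-fold lower and none was as much higher. The hyaluronan scavenger receptor gene stab2 stood at 1161 against 2648 CPM (ratio 0.439), the mannose receptor gene mrc1a at 562 against 1312 CPM (ratio 0.428) and dab2 at a ratio of 0.488 (0.476 to 0.5003), whereas fabp11a had a ratio of 1.41.

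The scavenging and lysosome list, which shares dab2, stab2 and mrc1a with the venous list, had 13 of 21 members at least 1.5-fold lower and none as much higher, and the cathepsin gene ctsla had a ratio of 0.694. Among 6 measured haematopoietic niche factors 4 were at least 1.5-fold lower, including the adhesion molecule gene vcam1b (29.3 against 110 CPM, ratio 0.267), the transcription factor gene tfec (ratio 0.449) and the selectin gene sele (ratio 0.663). Of these, tfec and sele also stand in the venous list. The chemokine gene cxcl12a had a ratio of 1.13. The lymphatic list went both ways, with 6 of 10 members at least 1.5-fold lower, such as lyve1b (ratio 0.664), and 3 higher, namely prox1a (2.19), vegfc (2.06) and lyve1a (1.69). Its lower members stab2, mrc1a, lyve1b and cdh6 also stand in the venous list.

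Median log2 ratios of the library labelled isl1-derived over the library labelled other, with their percentile among 10000 matched random lists of the same size, were 0.86 (percentile 100) for the arterial list, 0.83 (percentile 100) for the tip list, −0.59 (percentile 0) for the venous list, −0.68 (percentile 0) for scavenging and lysosome, −0.62 (percentile 0) for the lymphatic list and −0.76 (percentile 0.01) for niche factors. These percentiles describe the 2 libraries. With endothelial subclusters weighted equally, chosen for lists after seeing the data, the arterial median was −0.10 and the tip median 0.012. In that setting the venous, scavenging, lymphatic and niche medians were −0.18, −0.16, −0.22 and −0.18.

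Genes of Notch signalling and of DNA replication were also higher in endothelial-like cells of the library labelled isl1-derived. The Notch list had 8 of 18 members at least 1.5-fold higher and none as much lower. It shares dll4, hey1, hey2 and notch1b with the arterial list, so the 2 lists are not independent. Of its members, her15.1, a hairy-related target, stood at 78.2 against 14.2 CPM (ratio 5.497) and notch2 had a ratio of 2.27. The median of the Notch list was 0.57 (percentile 100). The G1/S list had 9 of 19 members at least 1.5-fold higher and none as much lower, with rrm2 at a ratio of 2.65, pcna at 1.80 and a median of 0.57 (percentile 100). The G2/M list had 3 of 18 higher, with plk1 at 1.73 and a median of 0.26 (percentile 99.9). The paraxial mesoderm list had 3 of 5 higher, with tcf15 at 4.47, foxc1b at 2.59 and a median of 0.73 (percentile 99.98). The posterior Hox list had 5 of 19 at least 1.5-fold lower, with hoxb13a at 0.436, hoxa11a at 0.476 and a median of −0.34 (percentile 0.19). Some of these medians shrank or changed sign in settings chosen after seeing the data. With subclusters weighted equally the Notch median was −0.078 and the VEGF median −0.15, and the G1/S and paraxial mesoderm medians were 0.00014 and 0.17. The G1/S median was −0.048 when subclusters with at least 5 cells of each library were included. With every cell thinned to 2000 UMIs the G2/M median was −0.029 and the posterior Hox median 0.0032.

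The remaining lists had medians nearer 0. VEGF signalling had 2 of 12 members higher and 2 lower (median 0.18, percentile 98.9), and BMP and TGF-beta signalling had 3 of 14 higher, with id2b at 1.87 (median 0.11, percentile 96.1). The haemogenic list had 3 of 7 higher, with runx1 at 2.69 and gata2b at 2.72 from 14 and 13 UMIs in the library labelled other (median 0.081, percentile 68.6). Across the alternative settings the BMP and TGF-beta median ranged from −0.18 to 0.24 and the haemogenic median from −0.15 to 0.56. Flow-responsive genes had 1 of 10 higher, cyp26b1 at 1.86 (median −0.079, percentile 35.2). The cardiopharyngeal and lateral mesoderm list had 5 measured members, of which isl1 was lower and tbx20 higher at 2.05 (median 0.0020, percentile 51.1). Dissociation and stress genes had 3 of 21 lower, with hsp70l at 0.551, while fosab had a ratio of 1.04 (median −0.032, percentile 37.5). Matrix genes had 1 of 14 lower, mmp2 at 0.615 (median −0.014, percentile 64.4), and junction genes had 2 of 16 higher, with cldn5a at 1.75 (median −0.15, percentile 9.41). Interferon and innate immune genes had 0 of 5 beyond 1.5-fold (median 0.0052, percentile 66.3), glycolysis had 2 of 14 higher, with eno1a at 2.76 (median 0.030, percentile 80.1), and nuclear oxidative phosphorylation had 0 of 19 beyond 1.5-fold (median 0.12, percentile 96.9). Of the 84 ribosomal protein genes 1 was beyond 1.5-fold, and none of the 13 mitochondrial genes was.

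**Figure D3:**
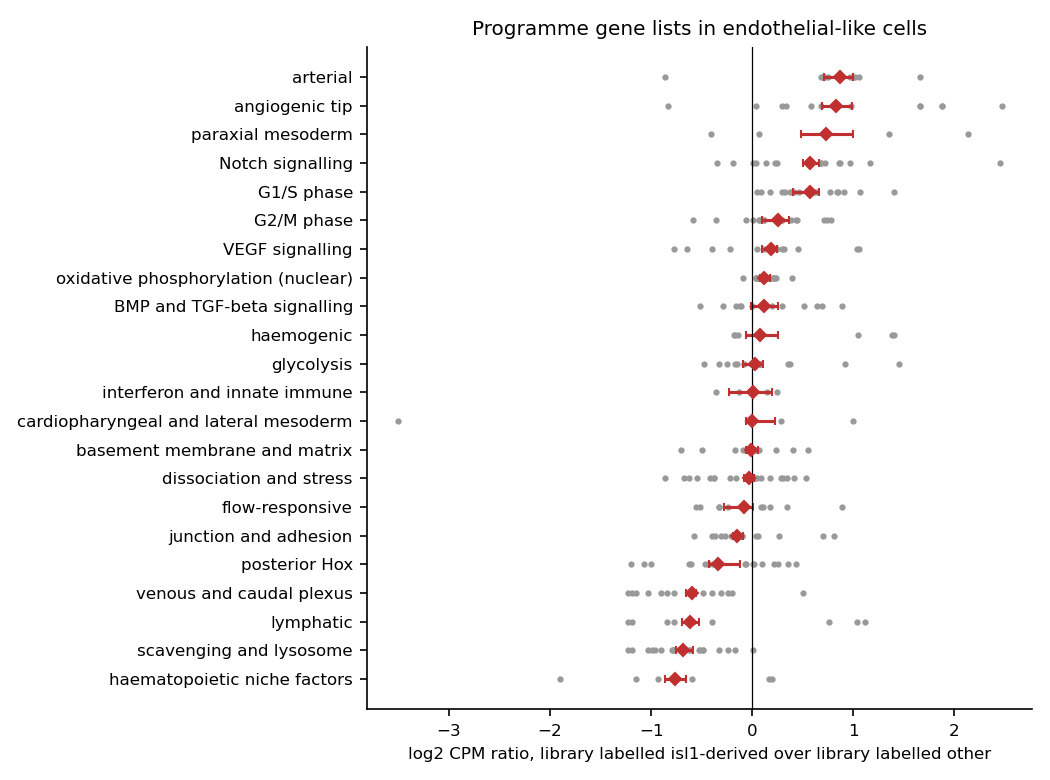
Log2 CPM ratio of the library labelled isl1-derived over the library labelled other in endothelial-like cells for members of 22 gene lists (grey points) and their median (red diamonds), with bars for the 95% counting interval of the median from 1000 Poisson resamples. The arterial list lies at 0.86, the venous list at −0.59 and the haematopoietic niche list at −0.76.

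Across all 9274 measured genes, 171 had a CPM ratio of 2 or more and 116 a ratio of 0.5 or less, so 59.6% of these genes were on the side of the library labelled isl1-derived. TMM scaling shifted every log2 ratio by 0.12 and gave 226 and 71 genes, a split of 76.1%. The sums held 10754267 and 4006960 UMIs. Genes were ranked by the interval bound nearest a ratio of 1. On the side of the library labelled isl1-derived the leading genes were pyyb, a peptide hormone gene with 168 UMIs against 0, which makes it at least 20.9-fold higher against 3 counts over the other library, and lyz (ratio 25.8). They were followed by her4.2, gch2 (ratio 8.91), cd81b (6.01), her2 (8.14), rgs5b (5.87), her15.1, her15.2 (5.07), the chemokine receptor gene cxcr4b (4.20), esm1 and gpm6ab (4.05). The ratio of her4.2 was 38.7 (6.80 to 1545) on 1 UMI in the library labelled other. On the opposite side stood isl1 itself, the metallothionein gene mt2 (ratio 0.126), TagRFP, crygn2 (0.172), grm5b (0.200), chodl (0.242), kcnd3 (0.207), vcam1b, ncam3 (0.264), nefmb (0.225), sost (0.307) and tnnt3a (34.2 against 109 CPM, ratio 0.313).

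Transcripts of blood cells were also higher in the library labelled isl1-derived. In endothelial-like cells, 7 of 9 erythroid markers were at least 1.5-fold higher in the library labelled isl1-derived, with hbae3 at 31.9 against 6.99 CPM and hbbe3 at 25.9 against 5.24 CPM, and lyz, a neutrophil gene, stood at 70.8 against 2.75 CPM. Of 4 measured myeloid markers 3 were higher, with lcp1 at a ratio of 3.16, while srgn had a ratio of 1.00. In the library labelled isl1-derived, lyz stood at a similar level in other classes, with 56.4 CPM in blood progenitor-like and 74.3 CPM in epidermal-like cells. There hbae3 stood at 17.9 CPM in epidermal-like cells and 23.6 CPM in the unnamed cluster. In the library labelled other these levels were 8.96 and 6.78 CPM, on 1 UMI each. In blood progenitor-like cells hbbe3 stood at 10.2 against 1.09 CPM, the latter on 1 UMI. Free RNA as a source of these blood cell transcripts was not tested. Of 6 blood progenitor markers measured in endothelial-like cells 3 were higher, with myb at a ratio of 2.09, and of 4 muscle markers 3 were lower, with actc1b at 0.415. Of 27 endothelial markers 3 were higher and 5 lower, and the junction gene cdh5 had a ratio of 0.930. Among 3 mural markers rgs5b and notch3 (ratio 1.82) were higher. Among 6 mesenchymal markers, 2 were lower, postnb at 0.526 and col1a1a at 0.502. No member was beyond 1.5-fold among 2 neural, 2 pronephric and 1 epidermal markers measured, gch2 was the 1 neural crest and pigment gene measured, and no notochord or gut endoderm marker was measured.

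**Figure D4:**
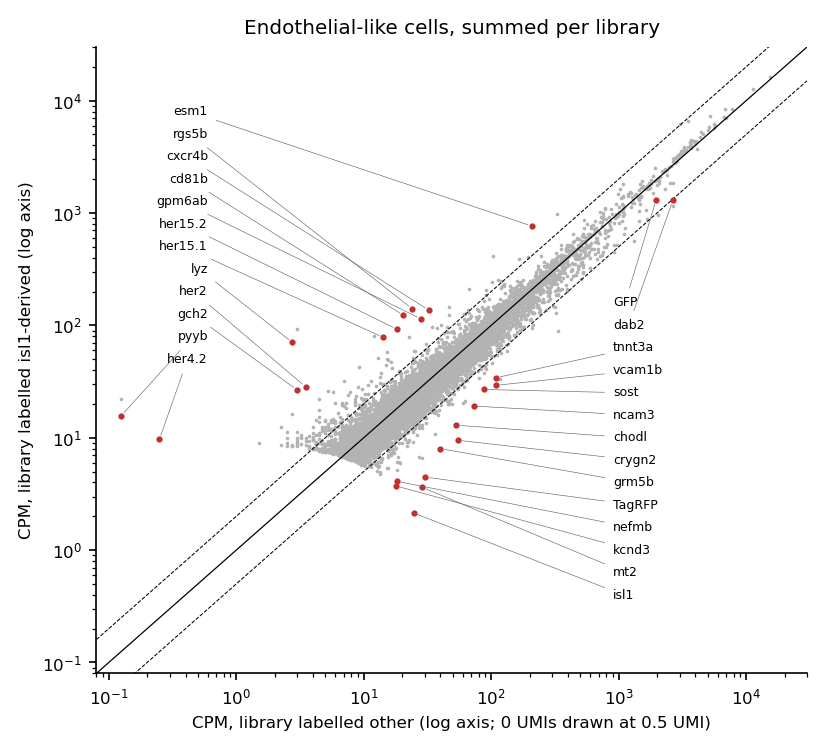
CPM of 9274 genes in endothelial-like cells of the library labelled other (x, log axis) and of the library labelled isl1-derived (y, log axis), with a solid line at equal CPM and dashed lines at ratios of 2 and 0.5. Named genes are red, with esm1 at 208 and 765 CPM, vcam1b at 110 and 29.3 CPM, and isl1 at 24.7 and 2.14 CPM.

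Clustering the endothelial-like cells alone gave 13 subclusters, which the libraries filled differently. Subcluster 1, led by apln, esm1, her15.1 and cxcr4a, held 21.4% (interval 19.2% to 23.8%) of the endothelial-like cells of the library labelled isl1-derived and 4.79% (3.15% to 6.94%) of those of the library labelled other. Subcluster 7, led by col14a1a, fbln2, gja5a and foxc1b, held 9.40% and 3.87%, and subcluster 11, led by gpm6aa and cxcr4b with efnb2a at 546 CPM, 4.58% and 1.105%. Subcluster 6, led by myca and replication genes such as mcm3 and mcm5, held 9.48% and 4.97%. The order was opposite in subcluster 2, led by crygn2, chodl, renbp, tnnt3a, lyve1b and sost, with 12.4% (10.6% to 14.3%) and 25.05% (21.5% to 28.9%), and in subcluster 3, led by megf6b, scn5lab and mrc1b with stab2 at 5402 CPM, with 9.72% and 19.0%. Subcluster 4 (col11a1b, slco1d1) held 7.31% and 14.2%, and subcluster 5 (sned1, hoxc13a, hoxa13a) 7.87% and 12.9%. Subclusters 8 (ldlrad2, vox, vegfc), 9 (histone genes) and 10 (ccnb1, cdc20) held 6.10% and 4.97%, 4.98% and 2.76%, and 3.29% and 4.97%.

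In total, 35.5% of cells would have to change subcluster for the 2 compositions to match (interval 31.6% to 40.1%), while 95% of simulated pairs with 1 shared composition stayed at or below 9.22%, which covers counting noise alone. The defining genes of these subclusters are among those that differ between the libraries. Clustering without the listed genes and without the genes at a ratio of 1.5 or more, an alternative chosen after seeing the data, gave 32.6%.

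**Figure D5:**
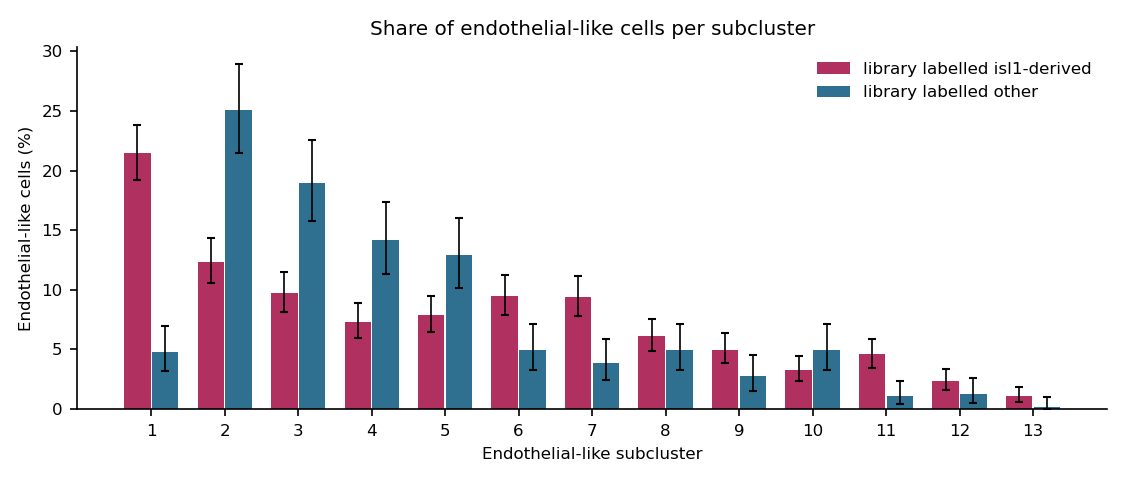
Percent of endothelial-like cells in each of 13 subclusters (bars) for the 2 libraries, with 95% exact binomial intervals. Subcluster 1 holds 21.4% and 4.79%, and subcluster 2 holds 12.4% and 25.05%, of the cells labelled isl1-derived and other.

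Within the single subclusters compared, the medians of the arterial and venous lists were smaller in size than in the sums, and some stayed low among random lists. These were subclusters 2, 3, 4 and 5, which held at least 50 cells of each library, and together 37.3% and 71.1% of the endothelial-like cells. Subclusters 1, 7, 8 and 11, where the arterial gene aqp8a.1 was highest, held too few cells of the library labelled other to be compared. It stood at 11467 to 16498 CPM in them and at 172 to 3328 CPM in the compared subclusters. Arterial medians of the compared subclusters were −0.19, −0.23, 0.14 and 0.15, each from 3 to 5 measured members, and do not cover the others. Their venous medians were −0.097, 0.043, −0.19 and −0.28, at percentiles 7.42, 88.3, 1.23 and 0.35. Scavenging and lysosome medians were 0.13 (percentile 99.6) and 0.092 (percentile 98.7) in subclusters 2 and 3, opposite to the summed −0.68, and −0.31 (percentile 0.01) and −0.30 (percentile 0.25) in subclusters 4 and 5. Lymphatic medians were −0.33 (percentile 0.01) and −0.45 (percentile 0.095) in subclusters 2 and 5, and −0.075 (percentile 32.5) and −0.16 (percentile 10.0) in subclusters 3 and 4.

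Dissociation and stress medians, near 0 in the sums, were 0.19 (percentile 99.9), 0.43 (percentile 100), −0.16 (percentile 4.82) and 0.022 (percentile 73.6) in the 4 subclusters. Mitochondrial genes had medians of 0.15 (percentile 98.2) and 0.34 (percentile 100) in subclusters 2 and 3, and nuclear oxidative phosphorylation genes −0.31 (percentile 0.26) in subcluster 3. The stab2 ratio was 0.776, 0.975, 0.768 and 0.690 in these subclusters, and the dab2 ratio 0.835, 0.938, 0.759 and 0.6996. In the 2 subclusters where it was measured, vcam1b had ratios of 0.595 and 0.552. Genes at a ratio of 2 or more numbered 8, 6, 2 and 8, and at 0.5 or less 13, 12, 12 and 9. The cxcl12a ratio was 2.40, 1.91, 0.624 and 0.637 in the 4 subclusters, and the aqp8a.1 ratio 0.666, 0.329, 1.42 and 1.22. In subcluster 2 hbae3 had a ratio of 8.38 (4.39 to 18.0), and crygn2 was lower at 0.355 and cdh6 at 0.391. In subcluster 3 tcima had a ratio of 3.11. In subcluster 5 spi2 had 181 UMIs against 1 (ratio 102, 18.1 to 4057), jdp2b had a ratio of 2.73 and apoeb of 0.462. The gene spi2 is also among the leading genes of the blood progenitor-like cluster led by pygma and il15ra, and of subcluster 12. How many cells held its 181 UMIs is not given, so a few cells with blood transcripts could account for them.

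Blood progenitor-like cells were the only other class with at least 50 cells in each library, with 555 and 69 cells. Their blood progenitor markers lay close, with 0 of 8 beyond 1.5-fold, such as myb (221 against 193 CPM, ratio 1.14) and lmo2 (ratio 1.15). Endothelial markers were lower in the library labelled isl1-derived in 19 of 23 cases, with cdh5 at 106 against 268 CPM (ratio 0.397) and mrc1a at 0.211. The arterial list, higher there in endothelial-like cells, was lower in this class in 8 of 8 members (median −0.97), as were 8 of 10 venous genes (median −1.40) and 10 of 11 matrix genes (median −0.98). The cluster of this class with cdh5 at 775 CPM held 128 of its 555 and 32 of its 69 cells. In the other blood progenitor-like clusters cdh5 stood at 39.1, 24.5 and 13.5 CPM. A difference in that mix could therefore give lower endothelial genes without a difference within clusters. It was not separated from these ratios, which are not read as differences within a cell type. G1/S genes lay close, with 0 of 20 members higher, 1 lower, and pcna at a ratio of 1.00, and 1 of 19 G2/M members was higher (median 0.11, percentile 99.1). The reporter ratios were 0.0799 (0.0405 to 0.158) for TagRFP, 0.522 for GFP and 0.361 for dab2, and isl1 had 4 and 8 UMIs.

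Among the genes with the largest ratios in this class, lyz (17.3, interval 5.90 to 84.2 on 3 UMIs in the library labelled other) and tcf15 (2.94) were higher in the library labelled isl1-derived, as in endothelial-like cells. The chemokine receptor gene ccr9a had 365 UMIs against 0 (at least 9.23-fold higher against 3 counts over the other library), ccl38.6 had 214 against 0 (at least 5.41-fold) and hbbe1.2 had a ratio of 16.2 (2.87 to 641) on 1 UMI. Other haemoglobin genes on this side were hbbe1.3 (6.79, 1.85 to 56.5, on 2 UMIs), hbbe3 (9.41, 1.66 to 375, on 1 UMI) and hbbe1.1 (9.03, 1.59 to 360, on 1 UMI). They were joined by s1pr4 (3.46), znfl2a (2.26), kcnd3 (3.39) and her15.1 (3.57). Lower were ldlrad2 (0.199), hspb9 (0.241), stab2 (0.261), ca16b (0.207), col14a1a (0.257), lyve1b (0.218), cavin1b (0.255), bcam (0.257), gpm6ab (0.234), XKR4 (0.306) and adgrl3.1 (0.301). Of 7730 measured genes, 127 had a ratio of 2 or more and 353 of 0.5 or less, and TMM scaling, which shifted log2 ratios by 0.28, turned this split around to 277 and 145. The same clusters held the class in different proportions. The cluster led by pygma and il15ra held 251 and 17 cells, and the cluster led by nptx1l, tnr and ldlrad2, in which cdh5 stood at 775 CPM, held 128 and 32.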

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

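The test of exchanged labels was chosen after the reporter levels were seen. The test of free RNA was set before its result was seen, and its form without 3 cells after.

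Cells outside the compared classes appeared above what a count of 0 allows. Neural-like cells were 3.13% of the library labelled other and 0 of 2023 cells in the library labelled isl1-derived. Cells of the mixed epidermal-like cluster were 1.78% and 2.42% of the libraries labelled isl1-derived and other. Cells of the erythroid-like cluster, which also carried blood progenitor markers, were 3.46% and 0.711%. The unnamed cluster led by tnnt3a made up 4.65% and 6.26%, and myeloid-like cells 1.14% of the library labelled isl1-derived. The neural-like cells had GFP at 68.8 CPM and dab2 at 74.1 CPM, against 1963 and 2660 CPM in endothelial-like cells of the same library, so they carried little of the RNA that the EGFP gate stands for.

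TagRFP and isl1 RNA ran against the labels, and free RNA at the rate of 20 other neural transcripts falls short of the endothelial-like TagRFP UMIs. The 20 had at most 2 UMIs in endothelial-like cells of the library labelled isl1-derived, a limit that TagRFP, with 48, fails. In the library labelled other they reached a median of 2.91% and at most 10.3% of their neural UMIs in endothelial-like cells. TagRFP reached 24.1%, which is 8.30 times that median (6.89 to 9.91) and above each of the 20. Without the 3 cells that held the most TagRFP UMIs it reached 14.8%, or 5.10 times (4.01 to 6.39). These intervals leave out the spread of the 20, and the test covers only free RNA that spread as they did. For isl1 the value was 17.0%, and 35 of its 99 endothelial-like UMIs remained without its 3 leading cells. Free RNA from another source stays open. In the library labelled other, TagRFP in blood progenitor-like cells, at 20.6 CPM (12.4 to 32.2), lay near the 30.4 CPM (25.3 to 36.4) of endothelial-like cells. For isl1 these classes stood at 8.68 CPM (3.75 to 17.1) and 24.7 CPM (20.1 to 30.1), with separate intervals. Without the 3 leading endothelial-like cells the latter was 8.81 CPM (6.14 to 12.3). At matched depth isl1 stood at 30.8 CPM (8.38 to 78.8), from 4 UMIs, and 31.2 CPM (21.3 to 44.0). An exchange of the 2 labels stays open. The endothelial-like ratios of 0.147 for TagRFP and 0.0866 (0.0525 to 0.137) for isl1 and the file names go with it. So do the 22 neural-like cells, with TagRFP at 2678 CPM and UMIs of it in 17 cells, which lay only in the library labelled TagRFP-negative. Both fractions are labelled EGFP-positive, however, and with GFP at 68.8 CPM these cells match neither gate at the RNA level. The ratios, the file names and the neural-like cells are the observations that raised the exchange and not a separate test. TagRFP protein set the gate while RNA was counted, and a biological difference between the sorted fractions was not tested.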

How the results depend on the processing

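No paired analysis was possible because each group is 1 library, and for the same reason no replicate could be left out and no other split of samples exists. Of the values that answer a comparison, 98 stayed within their counting interval or within 1.5 times the main count, 35 moved beyond it and 3 changed sign. Of the other values, 552 stayed, 160 moved and 10 changed sign. Of the 382 among them for named genes, 307 stayed, 75 moved and 0 changed sign. Where not stated otherwise, the cause was not tested. Under the other filters the numbers of kept cells stayed within 1.5 times 2023 and 703, and the neural-like shares stayed within their intervals under each filter and resolution. The composition difference of 35.5% was 35.0% and 37.1% at the other resolutions and 32.6% without the compared genes, within its interval. The unnamed cluster counted as endothelial and the high-UMI subcluster left out, both chosen after seeing the data, left both counts of endothelial-like genes within 1.5 times and the arterial and venous medians within their intervals.

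Without a barcode filter the endothelial-like log2 ratios were −3.41 for TagRFP and −0.99 for dab2, and endothelial-like shares were 66.7% and 84.0%. At resolution 0.5, where 1 cluster joined the erythroid-like class, blood progenitor-like shares were 21.4% and 7.54%. Thinning gave TagRFP shares of 1.09% and 2.92% of endothelial-like cells, as fewer UMIs per cell must.

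Endothelial-like genes at ratios of at least 2 and at most 0.5 (171 and 116) numbered 422 and 390 at a minimum of 30 UMIs and 62 and 47 at 300 UMIs, as other genes were measured. They were 94 and 62 with subclusters weighted equally, with 66 and 43 shared with the main genes, 90 and 69 when subclusters with at least 5 cells of each library were included, and 74 and 37 after thinning, with fewer genes measured. TMM scaling gave 71 on the lower side, and subclusters found without the compared genes gave 76. Blood progenitor-like counts (127 and 353) were 277 and 145 with TMM scaling, 558 and 1064 at 30 UMIs, 12 and 79 at 300 UMIs, and 270 and 636 with cells weighted equally.

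The arterial median (0.86) turned to −0.10 with subclusters weighted equally and −0.018 with those found without the compared genes, both chosen after seeing the data. Including subclusters with at least 5 cells of each library gave −0.080 and 0.024. The venous median (−0.59) was −0.18, −0.24, −0.18 and −0.28 in these settings, −0.47 with TMM scaling and −0.51 with cells weighted equally. With subclusters weighted equally the tip, scavenging, niche, lymphatic, G1/S and paraxial mesoderm medians shrank to 0.012, −0.16, −0.18, −0.22, 0.00014 and 0.17, the Notch median turned to −0.078 and the VEGF median to −0.15, and with those found without the compared genes the VEGF median was −0.17 and the G2/M median −0.49. Including subclusters with at least 5 cells gave VEGF medians of −0.097 and −0.025, a G1/S median of −0.048 and a G2/M median of −0.41. At 300 UMIs the paraxial median was 0.066. After thinning the posterior Hox median was 0.0032 and the G2/M median −0.029, against −0.34 and 0.26. Depth limits the library labelled other, with 69 blood progenitor-like cells and 921338 UMIs in them.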

Other observations

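The list medians under thinning and equal weighting were added after seeing the data, the weighting of subclusters found without the compared genes and those of subclusters with at least 5 cells after the first equal weighting had been seen, and the reading of the doublet test was settled after its value was seen.

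A blood progenitor-like cluster led by nptx1l, tnr and ldlrad2 carried genes of both blood progenitors and endothelium, with runx1 at 134 CPM, gata2b at 146 CPM, cdh5 at 775 CPM and kdrl at 335 CPM. It held 6.33% of the library labelled isl1-derived and 4.55% of the library labelled other, or 128 of 555 and 32 of 69 blood progenitor-like cells. The blood progenitor-like cluster led by pygma and il15ra had cdh5 at 39.1 CPM and myb at 279 CPM, and held 12.4% and 2.42%. An endothelial-like cluster led by ace, sdk1a and lyve1a had prox1a, a transcription factor gene of lymphatic endothelium, at 222 CPM and lyve1b at 1012 CPM, and held 1.73% (35 cells) and 0.427% (3 cells).

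The arterial list was higher and the venous list lower in endothelial-like cells of the library labelled isl1-derived, with the conflict over the labels still open. With every cell thinned to 2000 UMIs the medians were 0.94 and −0.60, so the greater weight of deep cells in the sums does not account for them. Thinning keeps each cell's expected proportions, and the classes were not formed again. An effect of depth on the classes was therefore not tested for either list. A different mix of subclusters is a candidate explanation for both, as weighting 9 subclusters equally gave −0.10 for the arterial and −0.18 for the venous list, and weighting 7 subclusters found without the compared genes gave −0.018 and −0.24, each under 0.5 times the pooled size. The first weighting is partly circular, as the compared genes helped to form the subclusters, and for holding under 20 cells of the library labelled other the first left out, among others, a subcluster led by gpm6aa and cxcr4b and the second, among others, one led by igsf5b and another led by her15.1 and esm1, but including all with at least 5 cells gave −0.080 and −0.18 in the first and 0.024 and −0.28 in the second clustering. Whether the mix differs between lineages or between gates was not tested.

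Subcluster 12 of the endothelial-like cells (29 and 7 cells), led by cebpa, ikzf1 and myb, combined cdh5 at 798 CPM with myb at 127 CPM and had a median of 18782 UMIs, against 7542 in the other endothelial-like cells. Doublets of an endothelial and a blood progenitor cell may form it, as of its measured genes 0.337% lay above 1.5 times the highest level of every other endothelial subcluster and blood progenitor-like cluster. That value does not separate doublets from other origins, because 6 of 11 other subclusters tested were also under 1%. Its median doublet score was 0.194, against 0.0411 in other endothelial-like cells, below the thresholds of 0.340 and 0.242. Its UMI median lay below the sum of both classes' medians, 28338, and cells between endothelial and blood states stay open as well.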
